A study of Homo sapiens with 3 samples.

How the data were processed

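RNA was profiled by sequencing in 3 populations of HCC827, an established cell line from a human non-small cell lung cancer with an activating mutation of the EGF receptor gene. Per the labels, the cells carried ClonTracer, a library of DNA barcodes, and were grown as a polyclonal pool. The vehicle population received 0.1% DMSO for 4 days. The erlotinib-resistant population received 2 µM erlotinib, an inhibitor of the EGF receptor kinase, for 47 days. The dual-resistant population was derived from the erlotinib-resistant population by a further 10 days in 2 µM erlotinib with 0.2 µM crizotinib, an inhibitor of the MET kinase. Total RNA was extracted with a column kit and made into Illumina libraries, per the labels' protocols. There was 1 library per group, so the 3 groups have no replicates.

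The deposited table gives gene expression as FPKM (fragments per kilobase of transcript and 1000000 mapped fragments), with 1 column per library. TopHat 1.3, Cufflinks 1.3 and the build GRCh37 are named per the submitters' processing notes. The gene set and its version, the strandedness of the libraries and the settings of the programs are not given in the sources used here. The table has 31402 rows, of which 23470 carry an Entrez gene ID and 7932 do not. It has 30866 distinct symbols, and 415 of them stand on more than 1 row. The missing cells number 35 in the vehicle column, 25 in the erlotinib-resistant column and 36 in the dual-resistant column, and were left out as missing. All 19 mitochondrial rows are at 0 in the 3 libraries, so mitochondrially encoded genes were not analysed here. Start positions in the table were taken to count from 0. Of the 58 rows that share their end with a RefSeq gene, 21 start 1 base before that gene's start and 3 at the same base, and the others start elsewhere. Coordinates are given from 1.

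The table holds no counts, so the depth is known only approximately. Single-exon protein-coding genes of 1 to 5 kb were picked by symbol from an annotation of another build, and percentile 1 of their values above 0, each multiplied by the gene's length in the table, was taken as the worth of 1 fragment. By this, 1 fragment in a gene of 1 kb was worth about 0.0146 FPKM in the vehicle library, 0.0211 in the erlotinib-resistant library and 0.0232 in the dual-resistant library. By this estimate a value of 1 FPKM in a gene of 1 kb stood on about 68.4, 47.4 and 43.0 fragments. The FPKM values summed to 596084, 528920 and 494817 over all genes.

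An exact 0 in this table can be a failed estimate and not a lack of RNA. Of the genes with at least 5 FPKM in both other libraries, 13 of 8401 were listed at 0 in the vehicle library, 11 of 8227 in the erlotinib-resistant library and 23 of 8484 in the dual-resistant library. A gene at 0 in a library compared is described as listed at 0 there, with no fold.

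From these values, rows that share a symbol were summed and the log2 difference of FPKM + 1 was taken between libraries, which understates the differences of low genes. Genes with at least 1 FPKM in at least 1 of the 3 libraries were compared, 13425 in all, less those with a missing cell. A gene that reached 1 FPKM in only 1 library is higher there by this filter alone, and the counts and list medians include such genes. With 1 library per group no test, p-value or standard error can be given. A gene is called higher or lower by size alone, at a log2 difference of 1 or more in either direction. A gene list was described by its median log2 difference and by the percentage of 10000 random lists of the same size, matched on mean expression in 10 bins, with a lower median. This percentage describes these libraries only. Medians of 11 neighbouring protein-coding genes with at least 5 FPKM in at least 1 library were taken along each chromosome and set against 1000 shuffles of the differences over the genes. Gene types and current symbols came from the RefSeq gene table, matched by Entrez ID. Its positions, which lie on another build, were used only to see from which base starts are counted, and no coordinates given here come from it.

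The 3 comparisons, the limits, 36 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The shuffles, the gene families and the tests in the closing section were chosen afterwards, and the rule for reading the shuffles was revised after their counts were seen. The rule named, for each comparison, the 10 highest and 10 lowest genes among those with at least 5 FPKM in at least 1 of the 2 libraries, leaving out small RNAs, histone, mitochondrial, unnamed, antisense and readthrough genes, pseudogenes, immunoglobulin and T cell receptor segments, XIST and Y-linked genes. It also named EGFR and MET, and for each list described up to 4 members with the largest difference in either direction. Because many of the highest and lowest genes were listed at 0, the 10 highest and 10 lowest among genes not listed at 0 were added after the values were seen. Some of the genes that the rule named are not reported here.

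The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a minimum of 5 FPKM, each library scaled to a sum of 1000000, each pair of libraries scaled to a median log2 difference of 0, a 4-fold limit, only the highest row of a symbol kept, 20 expression bins and windows of 21 genes. After the values were seen, counts without genes listed at 0, counts of protein-coding genes alone and a median share without genes listed at 0 were added. The steps were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data with 100 genes changed by a log2 difference of 2 and 100 by a log2 difference of 3 in each comparison. For the erlotinib-resistant library against vehicle, 100% of both were called in the right direction among 12576 genes. For the dual-resistant library against the erlotinib-resistant library the shares were also 100%, among 12560 genes, and for the dual-resistant library against vehicle 99% and 100%, among 12567 genes. Of 100 unchanged simulated lists, 0, 2 and 7 lay in the outer 5% of the random lists in these comparisons. The simulation assumed a small, independent spread of each gene and changed only genes with at least 5 FPKM in vehicle. Shares near 100% were therefore largely fixed in advance. The unchanged lists were drawn at random, unlike lists of genes regulated together. The simulation checks that the steps run as meant and cannot show how far real libraries differ without a change.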

Results

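Gene expression was measured by RNA sequencing in 3 populations of barcoded HCC827 lung cancer cells, with 1 library for each of the vehicle, erlotinib-resistant and dual-resistant populations. The values are FPKM as deposited by the authors. Of the genes in the table, 12386 had at least 1 FPKM in the vehicle library, 12143 in the erlotinib-resistant library and 12428 in the dual-resistant library. No group had a replicate, so every difference below is a difference between 2 libraries with no error estimate, and none has a test. Resistance, the drugs present and the length of treatment (4, 47 and a further 10 days) also differed together between the populations. Which of these a difference belongs to cannot be told apart here. The series was set up to profile the subpopulations behind resistance to an inhibitor of the EGF receptor and to an inhibitor of MET.

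EGFR, the receptor that erlotinib inhibits, and MET, the receptor tyrosine kinase that crizotinib inhibits, were followed in every library. EGFR (Entrez ID 1956, chromosome 7, 55086725 to 55275031, GRCh37) stood at 171 FPKM in the vehicle library, 885 in the erlotinib-resistant library and 698 in the dual-resistant library. MET (Entrez ID 4233, chromosome 7, 116312459 to 116438440) stood at 98.9, 763 and 96.2 FPKM. MET was thus 7.65-fold higher in the erlotinib-resistant library than in the vehicle library and 7.86-fold lower in the dual-resistant library than in the erlotinib-resistant library, on the FPKM + 1 scale used for all folds here. The dual-resistant and vehicle libraries differed little in MET, by a log2 difference of -0.04 as deposited and 0.23 with each library scaled to the same sum.

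**Figure D1:**
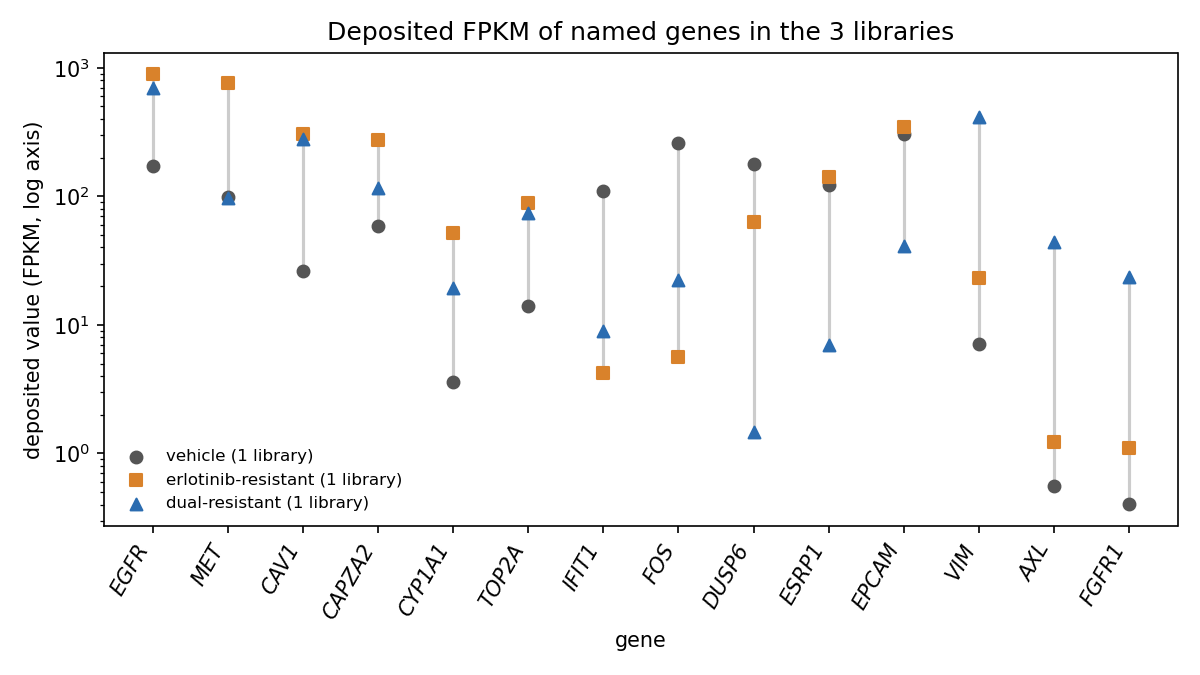
Deposited FPKM (vertical log axis) of 14 named genes (horizontal axis) in the vehicle (circle), erlotinib-resistant (square) and dual-resistant (triangle) libraries, 1 library each, with a grey line spanning the 3 values of a gene. MET stands at 763 FPKM in the erlotinib-resistant library and near 100 in the others, while VIM, AXL and FGFR1 are highest in the dual-resistant library.

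The first comparison asked what distinguished the erlotinib-resistant population from vehicle-treated cells. Most genes around MET on 7q31 (7 of 11, MET left out) were higher in the erlotinib-resistant library. So were most of the G2 and M phase list (28 of 33) and of the targets of the aryl hydrocarbon receptor (5 of 7). Lower were 28 of 33 interferon-response genes, 13 of 18 antigen presentation genes, 11 of 19 immediate early and heat shock genes, 11 of 20 lung lineage genes and 14 of 29 inflammatory mediators, of which the other 15 lay within the limit. In all, 510 genes were higher and 807 lower by at least 2-fold among 13381 compared, and 58 and 213 by at least 4-fold. Higher genes made up 38.7% of these calls. Scaling each library to the same sum moved that share to 54.6%, with 931 genes higher and 774 lower, and moved the median of all genes by 0.15 on the log2 scale. The directions of the lists described in the next 3 paragraphs did not turn under either scaling.

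Of the 7q31 list, which holds MET and its neighbours, 8 of 12 measured were higher and none lower. Its median log2 difference was 1.68, above 100% of the random lists. Without MET, 7 of 11 were higher, with a median of 1.58. CAV1, which encodes the main protein of caveolae (Entrez ID 857, chromosome 7, 115929906 to 116201239), was 11.2-fold higher, at 304 FPKM against 26.2. CAV2 was 6.39-fold higher and CAPZA2, a subunit of an actin capping protein, 4.63-fold higher. Of the EGFR neighbours on 7p11, EGFR alone of 14 measured members was higher, by 5.14-fold, and the list's median was 0.06. Other members of the ERBB list that were higher were the ligands NRG1, at 9.10 FPKM against 1.63, BTC, at 12.9 against 4.24, and EREG, at 144 against 56.8, so that 4 of 11 measured were higher and none lower. Of the G2 and M phase genes, 28 of 33 were higher and none lower, with a median of 1.35, above 100% of the random lists. TOP2A, the topoisomerase of dividing cells, was 5.91-fold higher, ASPM 3.76-fold, CDC20 3.75-fold and ANLN 3.56-fold. Of the S phase genes, 3 of 32 were higher and 1 lower, with a median of 0.15.

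Targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor, were higher for 5 of 7 measured and lower for none, with a median of 1.95, above 100% of the random lists. CYP1A1 stood at 51.5 FPKM against 3.57 and CYP1B1 at 21.8 against 1.33, both genes of xenobiotic-metabolising enzymes. NQO1 was 3.85-fold higher, and AHRR was listed at 0 in the vehicle library and stood at 3.15 FPKM in the erlotinib-resistant library and 8.47 in the dual-resistant library. Of the targets of NRF2, a regulator of the oxidative stress response, 5 of 20 were higher and none lower (median 0.62), with NQO1, UGDH and ABCC2 between 2.86-fold and 3.85-fold higher. NQO1 belongs to both lists and ABCC2 also to the drug efflux list, of which 2 of 12 were higher.

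Of the interferon-response genes, 28 of 33 were lower and none higher, with a median of -2.25, above 0% of the random lists. MX2 stood at 1.96 FPKM against 64.1, IFIT1 at 4.20 against 110 and OAS2 at 6.39 against 77.9, and IFI6 was 12.5-fold lower. Antigen presentation genes were lower for 13 of 18 and higher for 1 (median -1.25), with HLA-DRB1, HLA-B, CD74 and HLA-DMB between 3.94-fold and 6.48-fold lower. Of the NF-kB and inflammatory list, 14 of 29 were lower and none higher (median -0.86). Its members CCL20 and CXCL1, both chemokines, were 23.1-fold and 16.7-fold lower, SAA1 was 7.42-fold lower and the chemokine IL8 (now CXCL8) 6.80-fold lower. The immediate early and heat shock list was lower for 11 of 19 and higher for none (median -1.24), led by FOS at 5.60 FPKM against 261, FOSB at 0.602 against 50.5, EGR1 at 42.0 against 452 and NR4A1, which was 5.70-fold lower. Of the alveolar and lung lineage genes 11 of 20 were lower and none higher (median -1.20), with SLC34A2, AQP5, SFTPA2 and CEACAM6 between 3.96-fold and 6.14-fold lower. Squamous and basal genes were lower for 5 of 12 and higher for none (median -0.86), among them S100A7, SPRR2A, TP63 and SOX2. Hypoxia and glycolysis genes were lower for 6 of 26 and higher for none (median -0.52), with SLC2A3, a glucose transporter, at 0.344 FPKM against 15.6.

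Most of the 10 highest genes by the fixed rule were listed at 0 in the vehicle library. In the erlotinib-resistant and dual-resistant libraries, DDT stood at 56.8 and 71.6 FPKM, SMAGP at 49.4 and 17.3, TNFRSF6B at 42.8 and 9.47, and NUDT3 at 19.96 and 17.03. NME7 stood at 15.7 and 19.2 FPKM, KIAA0391 (now PRORP) at 13.6 and 19.3, MYL5 at 11.5 and 2.51, and RGP1 at 18.5 in the erlotinib-resistant library, with 0 listed in the dual-resistant library. CYP1A1 and CAV1 completed the 10. The 10 lowest were FOS, FOSB, CCL20, MX2, IFIT1 and GPNMB, the last at 2.81 FPKM against 68.7, with RPAIN, IGFBP7, ZSWIM7 and TMEM138, which were listed at 0 in the erlotinib-resistant library and stood at 31.3, 22.1, 18.5 and 16.96 FPKM in the vehicle library. IGFBP7 stood at 448 FPKM in the dual-resistant library, in which RPAIN, ZSWIM7 and TMEM138 were also listed at 0. Without the genes listed at 0 in either library, 437 genes were higher and 676 lower.

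**Figure D2:**
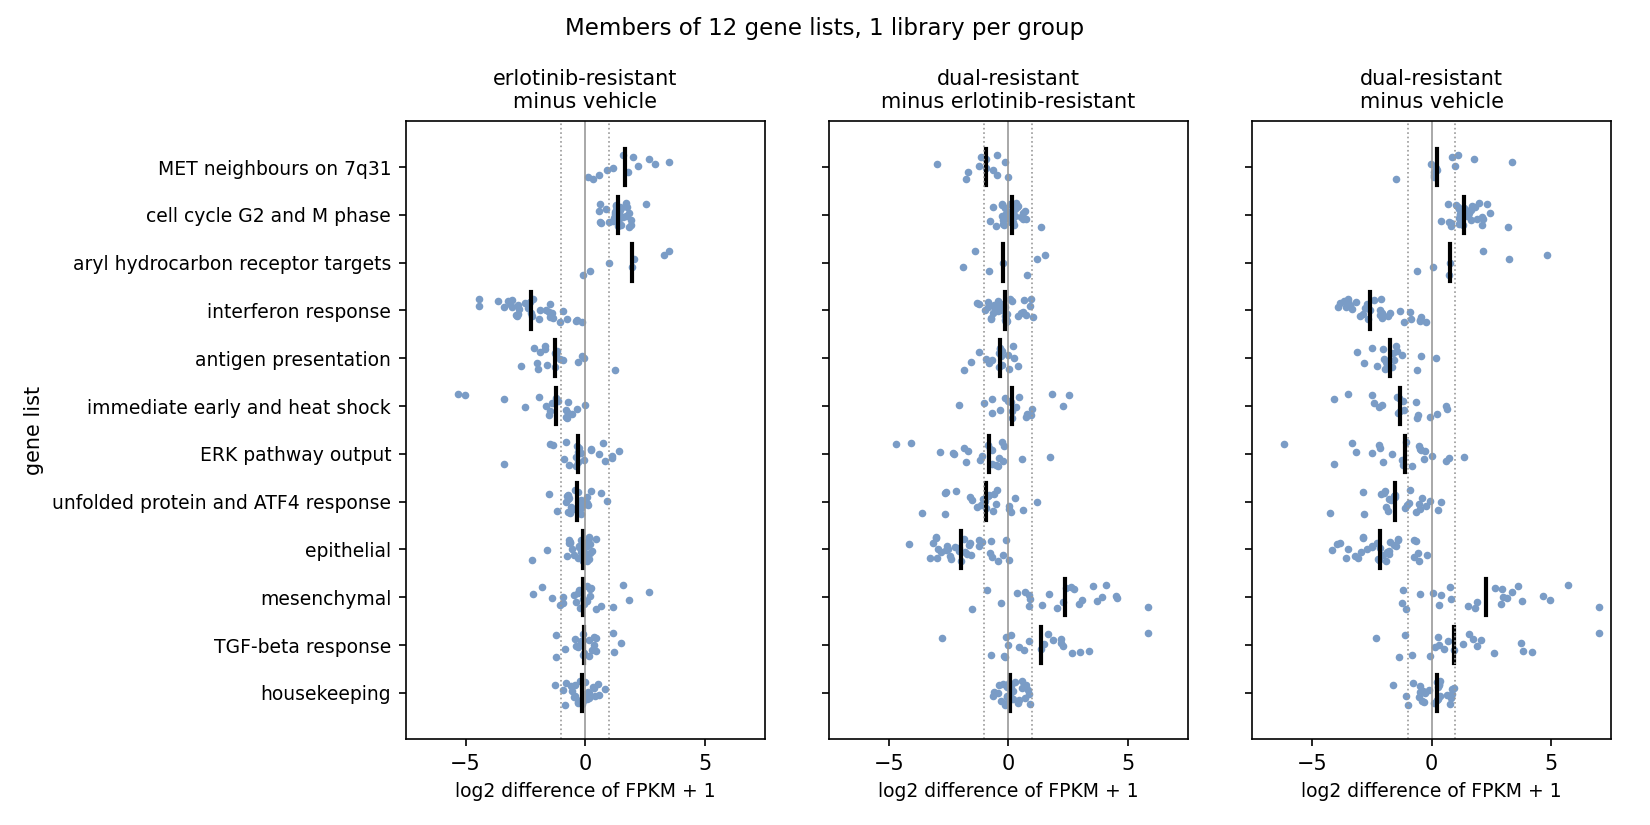
Log2 difference of FPKM + 1 (horizontal axis) for each measured member (dot) of 12 gene lists (vertical axis) in the 3 comparisons, 1 library per group, with the list's median as a black bar and dotted lines at a log2 difference of 1 in either direction. Interferon-response genes lie low in both comparisons with vehicle, with medians of -2.25 and -2.59, and epithelial genes lie low in both comparisons of the dual-resistant library, with medians of -1.99 and -2.16.

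The second comparison asked what distinguished the dual-resistant population from the erlotinib-resistant population it was derived from. In the dual-resistant library 26 of 33 epithelial genes and 10 of 22 genes of ERK pathway output were lower, and 16 of 24 mesenchymal, 11 of 21 TGF-beta response and 11 of 22 YAP and TEAD target genes were higher, while 11 of the ERK output genes and 9 in each of the TGF-beta and YAP lists lay within the limit. The receptor tyrosine kinases AXL and FGFR1 were higher while MET and ERBB3 were lower. In all, 1357 genes were higher and 967 lower by at least 2-fold among 13385 compared, and 391 and 251 by at least 4-fold.

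Of the epithelial genes, 26 of 33 were lower and none higher, with a median of -1.99, above 0% of the random lists. ESRP1, a splicing regulator of epithelial cells, stood at 7.01 FPKM against 141, the adaptor subunit AP1M2 at 9.74 against 103, the tight junction protein CLDN7 at 45.8 against 420 and the adhesion molecule EPCAM at 41.1 against 345. Of the mesenchymal genes, 16 of 24 measured were higher and 1 lower, with a median of 2.36, above 100% of the random lists. VIM, the intermediate filament vimentin, stood at 414 FPKM against 23.3 and the collagen chains COL6A2 and COL5A1 at 34.1 against 0.517 and 25.1 against 0.163. COL5A1 reached 1 FPKM in the dual-resistant library alone, so the filter fixed its direction. The TGF-beta response list was higher for 11 of 21 and lower for 1 (median 1.39). Among its members, COL4A1 was 10.3-fold and COL4A2 7.99-fold higher, and ID1 was 6.82-fold lower. COL4A1, too, reached 1 FPKM in the dual-resistant library alone. YAP and TEAD targets were higher for 11 of 22 and lower for 2 (median 0.99), with ANKRD1 at 144 FPKM against 2.90, DLC1 at 14.2 against 0.135 and NT5E lower, at 9.05 against 100.1. Alveolar and lung lineage genes were lower for 7 of 20 and higher for 3 (median -0.67), with MUC5B, a secreted mucin, at 0.0838 FPKM against 31.5 and NAPSA 7.45-fold lower. Squamous and basal genes were lower for 6 of 12 and higher for 1 (median -0.93), among them KRT15, SOX2 and SPRR1A, and SPRR1B, which was listed at 0 against 6.85 FPKM and stood at 7.74 in the vehicle library.

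Among other receptor tyrosine kinases and their ligands, 6 of 23 were higher and 5 lower. AXL stood at 44.4 FPKM against 1.23, its ligand GAS6 at 21.6 against 1.49 and FGFR1 at 23.4 against 1.10. In the ERBB list, 5 of 11 were lower and 1 higher. ERBB3 was 4.92-fold lower, the ligand AREG 3.82-fold lower and ERRFI1, a feedback inhibitor of the EGF receptor, 3.53-fold lower, and the ligand HBEGF was higher, at 30.2 FPKM against 1.35. EGFR differed by a log2 difference of -0.34. Of MET and its neighbours on 7q31, 5 of 12 were lower, MET among them, and none higher (median -0.94). Without MET the median of the other 11 was -0.92. CAV1 kept 280 FPKM against 304, a value named after it was seen. ERK pathway output was lower for 10 of 22 and higher for 1, with a median of -0.81, above 0% of the random lists. DUSP6 and DUSP5, phosphatases of the MAP kinases, stood at 1.48 FPKM against 63.6 and 5.22 against 103, and the transcription factors ETV4 and ETV5 were 7.21-fold and 5.03-fold lower.

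The unfolded protein and ATF4 list was lower for 11 of 25 and higher for 1 (median -0.92), with GDF15 at 26.3 FPKM against 328, ASNS, the asparagine synthetase, at 44.0 against 282, and DDIT4 and TRIB3 6.32-fold and 6.03-fold lower. Hypoxia and glycolysis genes were higher for 9 of 26 and lower for 1 (median 0.77). ADM stood at 116 FPKM against 8.95 and LDHA, a lactate dehydrogenase subunit, at 753 against 226, and VEGFA was 4.00-fold lower. Of the drug efflux transporters 4 of 12 were higher and none lower (median 0.66), with ABCB1 at 10.3 FPKM against 0.317. Of the stem cell and drug-tolerance markers 4 of 13 were higher and 3 lower, among them ALDH1A1, an aldehyde dehydrogenase, at 58.8 FPKM against 0.809, CD24 at 433 against 30.8, CD44 at 211 against 41.5 and KLF4 at 4.55 against 31.3. In the NF-kB and inflammatory list 8 of 29 were higher and 9 lower. LCN2, a secreted lipocalin, stood at 78.8 FPKM against 3107, whereas IL32, CCL2 and IL6 were 34.8-fold, 16.5-fold and 5.57-fold higher. The G2 and M phase list had 1 of 33 higher and none lower, and the interferon list had 1 of 33 higher and 2 lower.

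The 10 highest genes by the fixed rule included IGFBP7, which was listed at 0 in the erlotinib-resistant library, and NPPB, NNMT, THBS1, MATN2, ANKRD1, IL32, ALDH1A1 and TUBA1A. The natriuretic peptide gene NPPB stood at 142 FPKM against 0.534, the methyltransferase gene NNMT at 544 against 5.78 and THBS1, which encodes a matrix glycoprotein, at 318 against 4.82. The 10 lowest held 4 genes listed at 0 in the dual-resistant library, DEFB4A, SCNN1A, SPRR2D and FAM158A (now EMC9), which stood at 180, 112, 29.9 and 29.2 FPKM in the erlotinib-resistant library and at 788, 131, 32.2 and 27.4 in vehicle. The others were AGR2, at 1.07 FPKM against 180, S100P, at 0.341 against 92.8, AZGP1, at 0.428 against 80.5, S100A9, at 0.388 against 58.7, S100A14, at 0.890 against 64.5, and LCN2.

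The third comparison set the dual-resistant library against the vehicle library, across both steps of treatment. In the dual-resistant library 27 of 33 epithelial, 27 of 33 interferon-response, 15 of 18 antigen presentation and 12 of 22 ERK output genes were lower, and 15 of 24 mesenchymal and 28 of 33 G2 and M phase genes were higher. In all, 1470 genes were higher and 1397 lower by at least 2-fold among 13378 compared, and 424 and 468 by at least 4-fold. Higher genes made up 51.3% of these calls. Scaling each library to the same sum moved that share to 65.9%, with 2318 genes higher and 1202 lower, and moved the median of all genes by 0.25 on the log2 scale.

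Of the epithelial genes 27 of 33 were lower and none higher (median -2.16), and of the mesenchymal genes 15 of 24 were higher and 3 lower (median 2.27). LOXL2, a lysyl oxidase of the matrix, was 30.6-fold higher. Interferon-response genes were lower for 27 of 33 and higher for none (median -2.59), among them OAS1 at 9.19 FPKM against 150 and IFI27 at 252 against 3181. Antigen presentation genes were lower for 15 of 18 and higher for none (median -1.75), and G2 and M phase genes were higher for 28 of 33 and lower for none (median 1.34). ERK pathway output was lower for 12 of 22 and higher for 1 (median -1.12), with DUSP6 at 1.48 FPKM against 178 and EGR1 at 26.0 against 452. The unfolded protein and ATF4 list was lower for 15 of 25 and higher for none (median -1.53). YAP and TEAD targets were higher for 13 of 22 and lower for 2 (median 1.305), and TGFB2, a ligand in that list, was 13.2-fold higher. NRF2 targets were higher for 8 of 20 and lower for none (median 0.90), among them HMOX1, AKR1C3 and GCLM. Targets of the aryl hydrocarbon receptor were higher for 3 of 7 and lower for none (median 0.77). Among them, CYP1B1 stood at 64.6 FPKM against 1.33 and CYP1A1 at 19.2 against 3.57. In the dual-resistant library against the erlotinib-resistant library, 2 of these 7 targets were higher and 2 lower (median -0.23). Of MET and its neighbours 3 of 12 were higher and 1 lower (median 0.21), and without MET 3 of 11 were higher (median 0.24). The 10 highest genes included NPPB, THBS1, ANKRD1, MATN2, ALDH1A1, NNMT, VIM and SPP1, with DDT, which was listed at 0 in the vehicle library and stood at 71.6 FPKM. The 10 lowest were S100P, S100A9, LCN2, AZGP1, AGR2, SLPI and DUSP6, with DEFB4A, SCNN1A and CP, which were listed at 0 in the dual-resistant library and stood at 788, 131 and 70.3 FPKM in vehicle. CP stood at 3.54 FPKM in the erlotinib-resistant library.

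Other lists differed less or went both ways. In the erlotinib-resistant library against vehicle, none of 33 epithelial genes was higher and 2 were lower, among them PRSS8, and 4 of 24 mesenchymal genes were higher and 4 lower. ERK pathway output had 3 of 22 higher and 3 lower (median -0.28, above 2.44% of the random lists). The other receptor tyrosine kinases and ligands had 3 of 23 higher and 4 lower. In the same comparison, 2 of 22 p53 targets were lower (median -0.49, above 0.02% of the random lists). Of the unfolded protein and ATF4 list 2 of 25 genes were lower (median -0.35, above 1.77% of the random lists). Lower too were 1 of 10 NOTCH pathway genes and 1 of 21 BCL2 family and cell death genes, with none higher in these 4 lists. Cholesterol synthesis genes had 1 of 23 higher and 1 lower in that comparison and 5 of 23 higher, with none lower, in the dual-resistant library against the erlotinib-resistant library. WNT targets had 2 of 8 higher and 2 lower in both of these comparisons, and DKK1, a secreted WNT inhibitor, stood at 1.58, 9.83 and 54.8 FPKM in the 3 libraries. Neuroendocrine genes were measured for 6 of 18 and had 2 higher and 2 lower in the dual-resistant library against the erlotinib-resistant library, with NCAM1 at 9.46 FPKM against 0.135. Cytosolic ribosomal protein genes had none of 51 higher or lower in the erlotinib-resistant library against vehicle (median 0.02, above 99.16% of the random lists). In the dual-resistant library against the erlotinib-resistant library 1 of 51 was lower, RPS6 (median -0.36, above 0.1% of the random lists). Of the 27 housekeeping genes, B2M alone was called in the first comparison, at 947 FPKM against 2243, and none in the second. In the third comparison 2 of 27 were lower and none higher (median 0.24, above 99.62% of the random lists). An extreme percentage can thus go with a small median, also in these control lists.

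Markers of other cell types were mostly below 1 FPKM. Of the immune cell markers 5 of 21 were measured, of the fibroblast and endothelial markers 4 of 17, of the neural and melanocytic markers 4 of 16 and of the liver and gut markers 8 of 23. Fibroblast and endothelial markers were higher for 3 of 4 in the dual-resistant library than in the erlotinib-resistant library. Their median was 1.10, above 98.38% of the random lists. Against vehicle 3 of 4 were also higher (median 1.15), with none lower in either comparison. LUM and PDGFRB, however, reached 1 FPKM in the dual-resistant library alone, so the filter fixed their direction. With ENG and COL1A1 as the only others, these counts and the percentage cannot say whether such markers rose with the mesenchymal genes. In the vehicle, erlotinib-resistant and dual-resistant libraries, ENG stood at 8.75, 13.8 and 32.9 FPKM, COL1A1, which the mesenchymal list also holds, at 3.84, 2.48 and 5.38 and LUM at 0.0291, 0.0725 and 1.52, and PDGFRB was listed at 0 in the first pair of libraries and stood at 1.01 in the dual-resistant library. Among immune markers LCP1 stood at 116, 135 and 22.4 FPKM and CD68 at 45.5, 115 and 66.5 in the vehicle, erlotinib-resistant and dual-resistant libraries. In the neural list TUBB3 stood at 79.6, 50.1 and 207 FPKM, and in the liver and gut list FGB stood at 2.99, 0.335 and 24.5.

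Genes named for their place along the chromosomes were chosen after their values were seen. The highest median of 11 neighbouring genes in the erlotinib-resistant library against vehicle was 1.58, on chromosome 7 from 114562209 to 121036422, from MDFIC to FAM3C, with 7 of the 11 higher. The highest median in 1000 shuffles of the differences was 1.14. Overlapping windows above every shuffle reached farther on chromosome 7. At 11 genes they ran from 110303106 to 123197958, with 18 of 18 genes above 0. At 21 genes they ran from 102073996 to 127732659, with 48 of 52 genes above 0 and a median of 0.84. The lowest median was -1.53, on chromosome 4 from 71570654 to 74964997, a stretch that holds chemokine genes, with 6 of the 11 lower, and the lowest in the shuffles was -1.33. In the dual-resistant library against the erlotinib-resistant library the highest median was 1.503, on chromosome 17 from 35441927 to 36831187, from ACACA to C17orf96, with 9 of the 11 higher. It was reached in 10 of the 1000 shuffles, and the highest of these was 2.19. The same stretch of chromosome 17 had the highest median against vehicle, 1.78, with 10 of the 11 higher and 1 lower, and 12 of the 1000 shuffles reached it. The lowest median in the dual-resistant library against the erlotinib-resistant library, -1.09 on chromosome 16 from 69373415 to 70367731, was reached in 76 of the 1000 shuffles. The lowest median against vehicle was -3.13, on chromosome 1 from 153003679 to 153588808, from SPRR1B to S100A14, with 9 of the 11 lower, against a lowest of -2.25 in the shuffles.

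**Figure D3:**
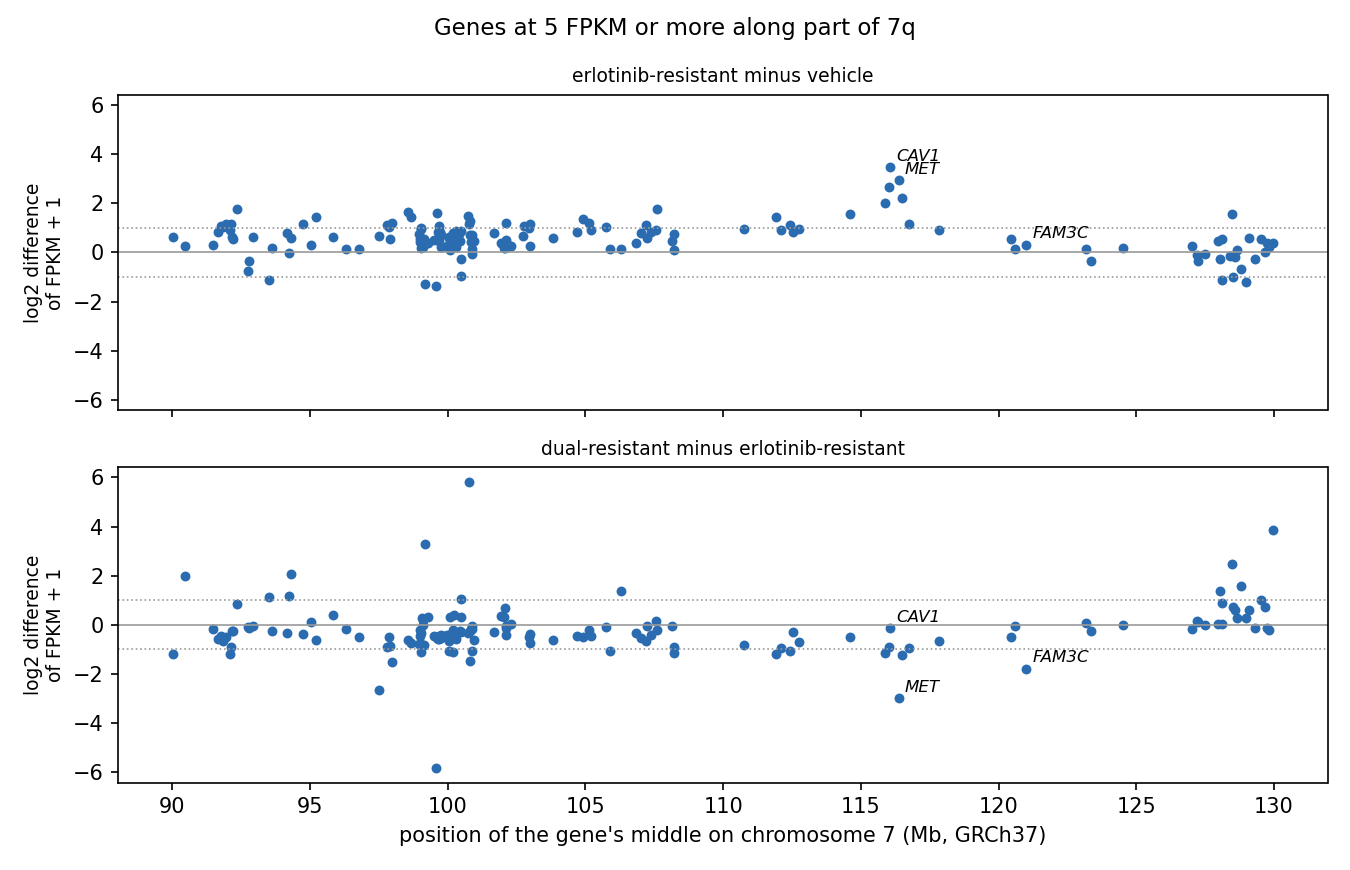
Log2 difference of FPKM + 1 (vertical axis) of protein-coding genes with at least 5 FPKM in at least 1 library (dots) by position along part of chromosome 7 (horizontal axis, Mb, GRCh37), for the erlotinib-resistant library minus vehicle (upper panel) and the dual-resistant minus the erlotinib-resistant library (lower panel), 1 library per group. The dots around CAV1 and MET reach 3.48 and 2.93 in the upper panel, and MET lies at -2.97 in the lower panel.

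**Figure D4:**
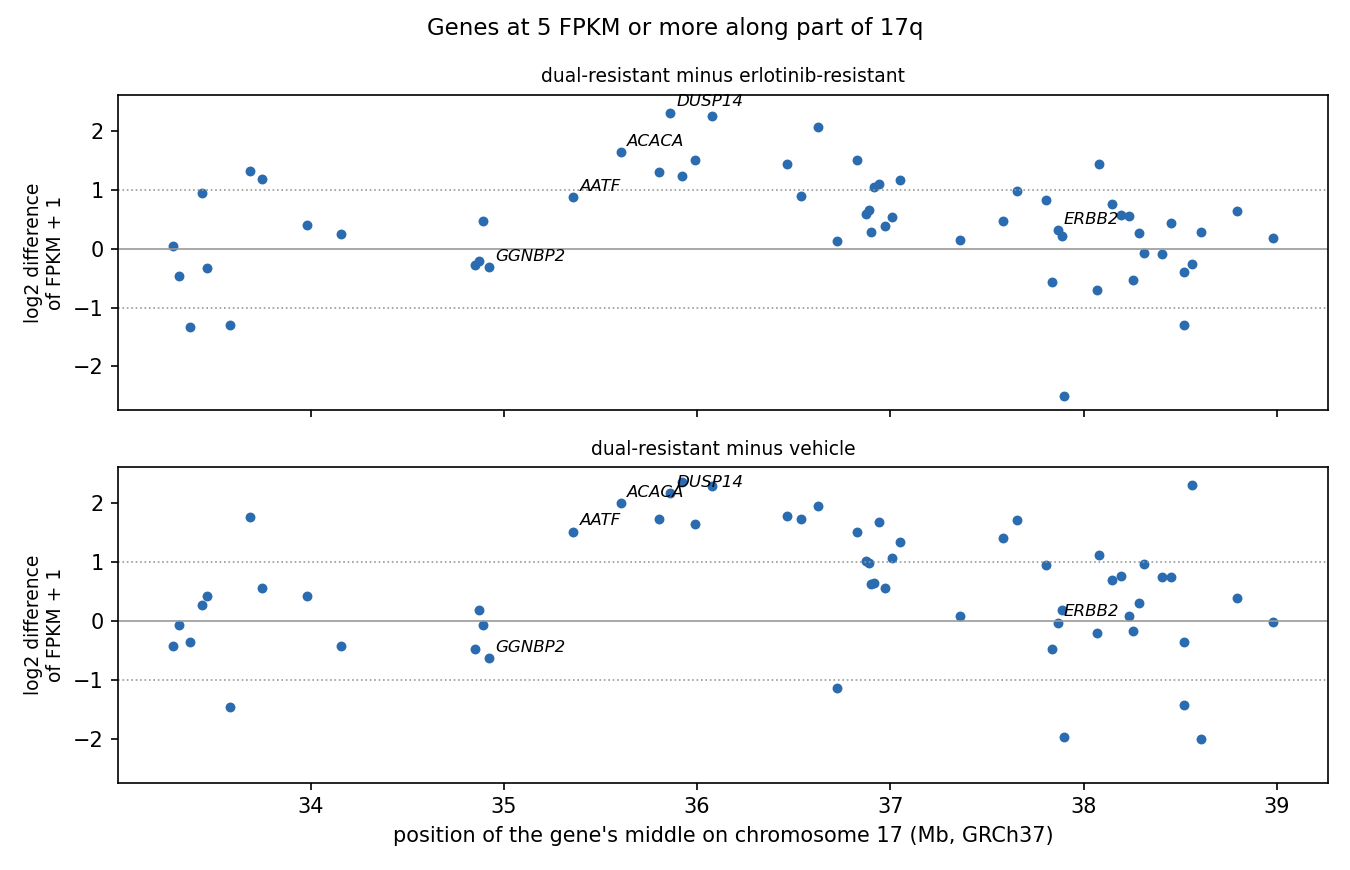
Log2 difference of FPKM + 1 (vertical axis) of protein-coding genes with at least 5 FPKM in at least 1 library (dots) by position along part of chromosome 17 (horizontal axis, Mb, GRCh37), for the dual-resistant library minus the erlotinib-resistant library (upper panel) and minus vehicle (lower panel), 1 library per group. Genes from ACACA to DUSP14 lie above 1 in both panels, AATF just before them lies at 0.87 and 1.52, and genes farther along, such as LASP1 at 1.16 and 1.34, are also high.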

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

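Leaving out a replicate was not possible with 1 library per group. No paired analysis was possible because each group has 1 library and the counts come from no test. Counts depended most on the pseudocount and the limit. With a pseudocount of 5, the erlotinib-resistant library had 167 genes higher and 355 lower than vehicle, the dual-resistant library had 592 higher and 457 lower than the erlotinib-resistant library, and 686 higher and 747 lower than vehicle. With a 4-fold limit the same counts were 58 and 213, 391 and 251, and 424 and 468. A larger pseudocount shrinks the differences of low genes and a wider limit passes fewer genes by construction. With a pseudocount of 0.1, 856 genes were higher in the erlotinib-resistant library than in vehicle. Scaling each library to a sum of 1000000 gave 931 genes higher in the erlotinib-resistant library and 2318 in the dual-resistant library than in vehicle. That scaling raised the values of every library against the pseudocount and moved the median of all genes by 0.15 and 0.25. In the other comparisons and settings, and in both added after the values were seen (without genes listed at 0, and protein-coding genes alone), each count was within 1.5 times the main count. Single genes were followed only where named as highest or lowest, with those added later, EGFR and MET. Genes named only as list members were not followed singly. Of these 85 differences of named genes, 69 moved by 1.5-fold or more with a pseudocount of 5 and 53 with a pseudocount of 0.1. Under the scaling to an equal sum 32 moved, and 0 under the scaling to an equal median. Both pseudocounts act most on folds that have a low value on 1 side. No list median of 2-fold or more changed sign under the pseudocounts, the scalings or the filter at 5 FPKM. Nor did any of these named-gene differences of 2-fold or more under the pseudocounts and scalings. For genes this was fixed in advance under the pseudocounts, which keep the sign of a difference. It was nearly so under the scalings, which moved the median of all genes by 0.25 at most. Of 105 list medians, 8 changed sign under the scaling to an equal sum and 7 under that filter, among them the liver and gut list of the dual-resistant library, whose median against the erlotinib-resistant library went from -0.72 to 1.20; the cause was not tested. With 20 expression bins, none of 105 list percentiles crossed into or out of the outer 5%. With windows of 21 genes, no shuffle reached the highest medians on chromosomes 7 and 17 in the 3 comparisons (1.10, 1.18 and 1.52), while at 11 genes some shuffles reached that of chromosome 17. The lowest medians lay elsewhere with 21 genes. For the erlotinib-resistant library against vehicle it was -0.67, which 5 of 1000 shuffles reached. For the dual-resistant library it was -0.89 against the erlotinib-resistant library, on chromosome 7 from LAMB1 to FAM3C, which 1 of 1000 reached, and -1.14 against vehicle, which 0 reached. Depth limits genes near 1 FPKM, for which about 43.0 to 68.4 fragments stand behind a gene of 1 kb.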

Other observations

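The gene families, the set of genes whose shares are given, and the tests in the paragraphs on neighbouring genes and on epithelial transcripts were chosen after the values were seen. Of 10 families examined, 4 are described. They share members with the fixed lists, so these genes are counted again here, 1 of 11 tubulin genes (TUBB3), 3 of 6 mucin genes (MUC1, MUC13 and MUC5B), 1 of 4 carcinoembryonic antigen genes (CEACAM6) and 6 of 17 collagen genes, among them COL5A1 and COL6A2. Tubulin genes were higher for 7 of 11 measured in the dual-resistant library than in the erlotinib-resistant library and lower for none, with a median log2 difference of 2.03 as deposited and 2.13 and 2.07 under the other scalings. TUBB6 stood at 99.2 FPKM against 14.1 and TUBB2A at 17.3 against 2.10. TUBB4A reached 1 FPKM in the dual-resistant library alone, so the filter fixed its direction. Tubulin genes have close copies, between which fragments can be divided wrongly. Mucin genes were lower for 6 of 6 (median -1.76), among them MUC16 at 6.01 FPKM against 23.6 and MUC20 at 0.508 against 6.60. The carcinoembryonic antigen genes were lower for 4 of 4 in the dual-resistant library than in vehicle (median -3.24), with CEACAM5 at 44.9, 7.21 and 0.781 FPKM in the vehicle, erlotinib-resistant and dual-resistant libraries. Collagen genes were higher for 11 of 17 in the dual-resistant library than in the erlotinib-resistant library and lower for 1 (median 1.91). COL17A1 was the lower one, at 2.52 FPKM against 15.5 in the erlotinib-resistant library, while COL12A1 and COL8A1 were higher, at 10.9 against 0.0710 and 6.75 against 0.0862. Of the 11 higher, COL12A1, COL8A1, COL27A1, COL4A1, COL4A3 and COL5A1 reached 1 FPKM in the dual-resistant library alone, so the filter fixed their direction.

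There were 30 protein-coding genes with at least 20 FPKM in the dual-resistant library and under 1 FPKM in vehicle. With the vehicle value subtracted, their level in the erlotinib-resistant library was a median of 1.48% of that in the dual-resistant library, with quartiles of 0.654% and 2.96%. The shares ran from -0.0399% for LEPREL1 to 79.4% for DDT. DDT was listed at 0 in the vehicle library, as was CRCT1, and C17orf81 and WRAP53 were listed at 0 in the vehicle and erlotinib-resistant libraries. Without these genes listed at 0 the median of the other 26 was 1.52%, with quartiles of 0.973% and 2.96%, and the highest share was 13.9%, for NR5A2. AXL lay at 1.53%, ANKRD1 at 1.53%, WISP2 at 5.62%, SPP1 at 5.01%, ALDH1A1 at 1.22% and NPPB at 0.338%. Many of these shares rest on small differences of low values between single libraries, so each share is rough. In the erlotinib-resistant and vehicle libraries AXL stood at 1.23 and 0.555 FPKM and COL5A1 at 0.163 and 0.0182.

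The stretch of 7q that was higher in the erlotinib-resistant library spanned MET, and unrelated differences of single genes were argued against, since 0 of 1000 shuffles reached its median of 1.58. A scaling difference between the libraries would move all genes alike, and the median of all compared genes was 0.00095. FPKM are already scaled to mapped fragments, so a median near 0 was likely in advance and adds little. A higher dose of the region may account for it as a hypothesis. Of the 7q31 list, fixed before the data were examined, 11 of the 11 measured members other than MET lay above 0. Their median was 1.58, against a median of 0.04 for the 7p11 list without EGFR. These members are nearly the same genes as the stretch, so they add little to it. They cannot tell a higher dose from shared regulation, which could also raise neighbouring genes together. In the dual-resistant library 7 of 21 genes of 7q from LAMB1 to FAM3C were lower than in the erlotinib-resistant library and none higher, with a median of -0.89 that 1 of 1000 shuffles reached, while CAV1 differed by -0.12. Shared regulation of the region stays open, since DNA copy number was not analysed here.

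The stretch of chromosome 17 that was higher in the dual-resistant library held ACACA, DUSP14 and MRPL45, named after their values were seen. A scaling difference between the libraries would move all genes alike. The median of all compared genes was -0.026, which was likely in advance for FPKM and adds little. At 21 genes 0 of 1000 shuffles reached the median of 1.18, the highest being 1.004, which argues against unrelated differences of single genes when the 12 extremes looked at over both sizes are allowed for, but at 11 genes 10 of 1000 reached the highest median, which by itself leaves such differences open. The rule for reading these counts was revised more than once after they were seen, and its earlier forms, at 11 genes alone, did not exclude unrelated differences, so the argument rests on the larger size and on the last form of the rule. A higher dose of the block could also give it, with 9 of the 11 genes higher, but the block was picked for these values and cannot test that, while the nearest genes measured before the 11 lay at -0.28 (ZNHIT3), -0.21 (MYO19), 0.46 (PIGW), -0.31 (GGNBP2) and 0.87 (AATF) and genes beyond them went both above and below 1, with LASP1 at 1.16, CDK12 at 0.98 and MLLT6 at 0.59.

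Epithelial transcripts that remained in the dual-resistant library could come from leftover cells with the erlotinib-resistant profile. If these were the sole source, every epithelial gene would keep the same share of its erlotinib-resistant level. The shares of the 30 epithelial genes with at least 10 FPKM ran from 4.99% to 103%, with a median of 23.5%, and their upper quartile was 3.70 times the lower, against 1.60 for 26 housekeeping genes, which argues against leftover cells as the sole source. Leftover cells as the source of part of these transcripts stay open. With an unchanged profile, though, they could supply each gene with no more than the lowest share seen, 4.99% for ESRP1 in this list. Of 1451 genes at 50 FPKM or more in both other libraries and above 0 here, the lowest share was 0.367%, for S100P. That gene was picked as the extreme and stood at only 0.341 FPKM in the dual-resistant library, so this limit is rough. Whether the difference arose within cells or by outgrowth of cells already present was not tested, and barcodes were not analysed here.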
